A study of Mus musculus with 68 samples.

How the data were processed

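Growth plate cartilage, the layer of chondrocytes that lengthens long bones, was studied in mice of mixed background at postnatal day 2 (P2), day 3 (P3) and day 28 (P28). Per the labels' protocols, bones were snap-frozen in embedding medium, cut at 10 microns and stained, and cells of the resting, proliferative and hypertrophic zones were picked by laser capture. The picked cells went straight into lysis buffer without RNA extraction, and libraries were made by SMART-seq2, a full-length cDNA method for small inputs, with Tn5 tagmentation, per the same protocols. Most sections were fixed in ethanol and 14 libraries came from xylene-fixed sections, per the labels.

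The deposited table holds the authors' raw counts, whole numbers of reads per gene symbol, for 23420 gene symbols in 100 columns. Per the submitters' processing notes, cutadapt, STAR 2.5.2b, featureCounts 1.5.3 and Subread were used with the mouse build mm10. The gene annotation, the handling of reads that map to several places and the strand setting are not given in the sources used here. SMART-seq2 does not mark strand, so a gene and an overlapping antisense gene cannot be told apart, and near-identical copies may share reads. The columns belong to 68 libraries. Of these, 36 have 1 column and 32 have 2 columns under one title; the 2 columns were compared gene by gene with a chi-square test, differed about as much as sampling gives (at most 1.03 per gene, apart from 3 pairs with 6 to 47 counted genes, where it reached 1.299), and were summed as repeat runs of 1 library. Libraries with a coded description (36, called set A here) and those without (32, set B) were treated as separate deposit sets, and both sets hold both ages.

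Animals were taken from the labels. Labels that differ only in a trailing number or side were counted as 1 animal, since the labels do not say that the suffix marks another one. The labels of P2 animal D and P28 animal B name animals in the plural, so each of these can be a pool, and counting each as 1 goes against that wording. P2 animal G and the P3 animal have labels that differ by 1 digit and a side, and were kept apart. The resting library of P2 animal G holds 128 Xist and 747 Y-linked counts, so whether it comes from 1 animal is in doubt. Without this animal the P2 counts that use its resting library fell, from 18 to 5 for resting against proliferative and from 262 to 54 for resting against hypertrophic. The count of hypertrophic against proliferative at P2, where its libraries hold 0 Xist counts, fell from 161 to 28. Ethanol-fixed P2 and P28 libraries with at least 100000 counts entered the tests. This minimum was set on all counts, those of the symbols Rn45s, Lars2 and Glra2 included. Without these symbols, P28 hypertrophic replicate 8 and P2 hypertrophic replicate 3, which entered, held 13080 and 20032 counts. P28 resting replicate 2, which did not enter, held 63512. Of the 51 ethanol libraries of these ages, 25 fell under the minimum. The remaining 26 libraries were summed per animal and zone into 21 sums, from 6 P2 and 3 P28 animals counted in this way. Xylene libraries and the single P3 animal were kept for description and for alternatives.

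Counts were tested in R 4.3.3 with edgeR 4.0.16: TMM normalization, filterByExpr, and the robust quasi-likelihood F-test with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Zone comparisons came from 1 fit over all sums, with the animal as a block and a zone effect within each age, which left 8 residual degrees of freedom. The zones of one animal share that animal per the labels, which is where the pairing comes from. As a check, deviations from the group means correlated between zones of the same animal by -0.00358 to 0.187. Differences between the ages in a zone effect were tested as interaction contrasts in the same fit. Ages were compared within each zone over the sums of that zone, with the deposit set as a term, which left 4 residual degrees of freedom per zone. Sex was not a term. Tested resting libraries of P2 animal A and P28 animals A and B held Xist and 0 Y-linked counts. Those of P2 animals D, F and G and P28 animal D held more Y-linked than Xist counts. Sex is thus uneven over the ages and cannot be fully told apart from age. Among the genes named with age, Gpc3, Zfp275, Chrdl1 and Glra2 lie on the X chromosome. The p-values rest on spread between these animals, with the dispersion of each gene moderated by that of the other genes. They can thus be far smaller than 4 or 8 residual degrees of freedom of 1 gene alone would give. Standard errors are the log2 fold change over the square root of the F statistic. Levels are TMM-normalised CPM (counts per 1000000), as mean ± SD over animals. Values of single libraries are CPM over the total of the library, without TMM, unless another base is named.

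Before the data were examined, 28 gene lists, covering zones, processes and markers of other cell types the capture could hold, were fixed, and 560 of their 565 symbols were found in the table, older symbols included. Lists with at least 5 tested members were tested with camera of limma 3.58.1 at an inter-gene correlation of 0.01, Benjamini-Hochberg adjusted over 196 tests of lists and comparisons. The tests were repeated with an estimated correlation and with fry. Of the 56 list tests past the threshold at the preset correlation, 0 remained with an estimated correlation, and fry had 22 past it. Counts of list members past the threshold are given over all genes tested and adjusted over the list alone.

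Genes named in the text follow a rule also fixed then. It takes, for each comparison, the 6 highest and 6 lowest log2 fold changes past the threshold with an average log2 CPM of at least 4 and the same sign in every animal with both zones, or in both deposit sets. It adds up to 3 members of each list with the smallest adjusted p, and Pthlh, Sfrp5, Ucma, Col2a1, Ihh, Pth1r, Col10a1, Mmp13, Mki67, Ptch1, Gli1, Igf2 and Nt5e wherever tested. Resting against hypertrophic is described by counts, lists and this last set, and genes beyond about 30 per comparison were left out. Where a group held 0 counts of a gene, the fold is a lower bound against a floor of 3 counts over the group; with 1 to 3 counts it is the ratio of pooled CPM with an exact 95% interval. Reads made by PCR without molecular identifiers are not independent molecules, so these intervals and bounds cover counting error only. Positions are from the GENCODE vM21 annotation of GRCm38, the assembly called mm10; the table gives symbols only.

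The edgeR test of each comparison was also run on simulated data with seeded fold changes. These were drawn from 1 mean per gene over all sums of the fit, with the real library sizes and dispersions. They thus held no differences between animals, zones, ages or deposit sets other than the seeded ones. Changed genes that the filter then dropped count as not recovered. For hypertrophic against proliferative at P2, 0% of genes changed 4-fold, 16.4% of those changed 16-fold and 51.5% of those changed 64-fold were recovered. After the filter 5662 genes were tested there. For resting against proliferative the shares at 16-fold and 64-fold were 23.9% and 60.6% at P2 and 11.9% and 53% at P28. For hypertrophic against proliferative at P28 they were 4.48% and 33.3%. For the ages they were 34.3% and 63.6% in resting, 32.8% and 57.6% in proliferative, and 62.7% and 80.3% in hypertrophic sums. The age difference of resting against proliferative recovered 0% and 22.7%, and that of hypertrophic against proliferative 2.99% and 25.8%. Unchanged genes called were 0 or 1 in each zone comparison, 3, 2 and 6 for the ages in resting, proliferative and hypertrophic sums, and 3 and 0 for the 2 age differences, the 3 beside 15 changed genes recovered at 64-fold.

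Alternatives fixed in advance were another normalization (RLE), no or a stricter filter on low counts, DESeq2 1.42.0, a test that is not robust, limma voom on single libraries with quality weights, other count or gene minimums, animal labels as given, added xylene libraries, the P3 animal counted with P2, set A alone, no deposit set term, no replicate block, and each animal left out in turn. After the data were seen, 4 more were added: without the symbols Rn45s, Lars2 and Glra2, without each of a pair of doubted libraries of P28 animal D, and with all sums thinned to the lowest total. A minimum of 1000000 counts and set B alone left too few animals and were not run.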

Results

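The data are 68 laser-captured libraries from growth plate cartilage. The resting zone holds slowly dividing reserve chondrocytes, the proliferative zone columns of dividing cells, and the hypertrophic zone enlarged cells that precede bone. The design sets the 3 zones against each other at P2 and P28 and the ages against each other in each zone. Of the ethanol libraries, 9 were P2 resting, 8 P2 proliferative, 8 P2 hypertrophic, 8 P28 resting, 9 P28 proliferative and 9 P28 hypertrophic. A single P3 animal gave 3 more, and xylene-fixed P28 sections gave 4 resting, 5 proliferative and 5 hypertrophic libraries.

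Depth varied widely, from 748 to 3347722 counts per library. The median was 97514 in P2 resting, 110562.5 in P2 proliferative, 172133.5 in P2 hypertrophic, 89644.5 in P28 resting, 179653 in P28 proliferative and 121510 in P28 hypertrophic ethanol libraries. The 21 sums per animal and zone that entered the tests held 4 animals per zone at P2 and 3 at P28; 3 animals at each age had all zones. Rn45s, the 45S ribosomal RNA precursor, took a large share of the counts: its median share was 59.3% in P2 hypertrophic, 41.4% in P2 proliferative and 32.3% in P2 resting libraries. At P28 it was 41.7%, 32.7% and 30.3% in the same order. In the hypertrophic zone Rn45s rose against the proliferative zone by 1.94 ± 0.28 on the log2 scale at P2 and 1.39 ± 0.28 at P28, with Lars2, a mitochondrial leucyl-tRNA synthetase whose locus holds ribosomal repeats.

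**Figure D1:**
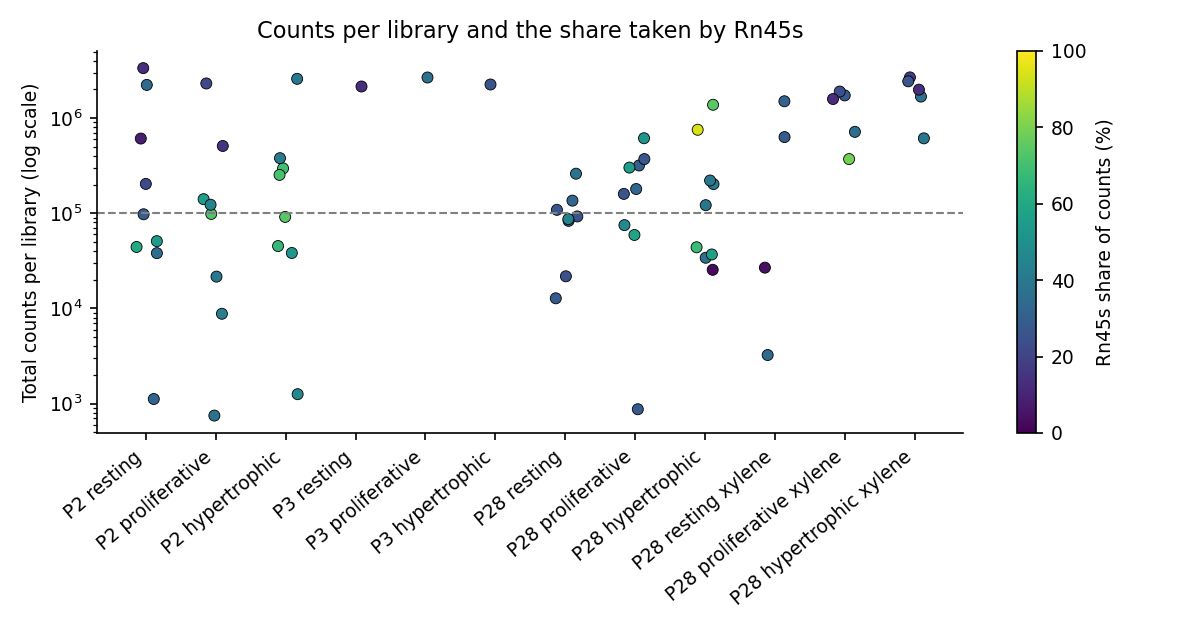
Total counts of each library on a log10 axis, by age, zone and fixation, coloured by the percent of counts taken by Rn45s; the dashed line is the minimum of 100000 counts. Each point is 1 library, and 27 of the 68 lie under the line.

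The resting zone supplies the columns of the proliferative zone, and few genes separated them at P2. Dcn and Col3a1, of the perichondrium and fibroblast list, were among those higher in resting, and Alpl, Panx3 and Pth1r, of the prehypertrophic and hypertrophic list, among those lower. Decorin (Dcn), a small proteoglycan that binds collagen, was 1376 ± 1044 CPM in resting and 20.1 ± 26.3 CPM in proliferative sums (SD, n = 4 each) and rose by 6.08 ± 0.99 on the log2 scale. Col3a1, a fibrillar collagen of soft connective tissue (5.27 ± 1.32), Fgfr1, a fibroblast growth factor receptor (3.91 ± 0.98), Srpx2 (7.28 ± 1.85) and the imprinted non-coding RNA Meg3 (2.68 ± 0.63) rose too. Serpine2, a serine protease inhibitor, had 2 counts in the proliferative sums, a pooled ratio of 364 (100.7 to 3011). Fat3, an atypical cadherin with 0 counts there, was at least 83-fold higher. Lower in the resting zone were Panx3, a channel protein of prehypertrophic chondrocytes (-5.99 ± 0.94), Pth1r, the receptor for PTHrP (-2.31 ± 0.57), Comp, a matrix protein of cartilage (-2.73 ± 0.53), Ppa1, a pyrophosphatase (-5.13 ± 0.91), and Lsp1 (-6.23 ± 1.34). The growth factor Gdf10 and the cytokine Il17b had 0 counts in the resting sums and were at least 1063-fold and 352-fold lower. Alpl, the phosphatase needed for mineralisation, had a pooled ratio of 0.0114 (0.00135 to 0.0423). Pcsk6, a proprotein convertase, fell by 5.71 ± 1.32 within animals, while 274 of its 275 resting counts came from P2 animal F, which has no proliferative sum.

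In all, 18 of 6958 genes passed the threshold, 7 higher and 11 lower in resting, with adjusted p of 1.62e-06 to 0.0327 for the named ones (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 3 animals with both zones). Not past it were Ucma at 2.45 ± 0.73, Col2a1 at -0.04 ± 0.35, Igf2 at 0.01 ± 0.53, Mki67 at -0.69 ± 0.98 and Sfrp5 at 1.42 ± 1.70. Pthlh, which encodes PTHrP, was found in 3 of 4 resting sums, 120 counts against 0. RLE scaling gave 1 higher and 11 lower. The count was 5 without P2 animal D, 5 without P2 animal G and 39 without P28 animal D. Of the 16 named genes 2, Gdf10 and Panx3, passed in every fit with 1 animal left out.

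Among the lists, prehypertrophic and hypertrophic markers leaned lower in resting (camera, Benjamini-Hochberg adjusted p = 9.67e-06, against 0.176 with an estimated correlation). Of 18 tested members 3 fell over all genes and 5 adjusted over the list alone. The perichondrium and fibroblast markers, which mark another tissue than the growth plate's cartilage, had 2 of 7 members higher, Dcn and Col3a1, and 4 higher and 1 lower adjusted over the list alone (adjusted p = 8.03e-04, camera with Benjamini-Hochberg; adjusted p = 0.251 with an estimated correlation). Of the resting zone markers 17 were tested, 0 rose and 1, Gdf10, fell over all genes, against 4 higher and 1 lower adjusted over the list alone. This list leaned higher as a whole (camera, Benjamini-Hochberg adjusted p = 0.0175; adjusted p = 0.35 with an estimated correlation). Cholesterol synthesis, amino acid response and one-carbon, and cytosolic ribosomal protein genes leaned lower in resting, with 0 members past the threshold over all genes or adjusted over the list alone. Their camera adjusted p values (Benjamini-Hochberg) were 2.28e-05, 2.22e-04 and 4.14e-04, against adjusted p = 0.335, 0.14 and 0.496 with an estimated correlation. GH and IGF pathway genes and imprinted and juvenile growth genes leaned higher (camera, Benjamini-Hochberg adjusted p = 0.00387 and 0.0192; adjusted p = 0.172 and 0.352 with an estimated correlation), with 3 and 3 members higher adjusted over the list alone and 0 and 1, Meg3, over all genes.

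Against the proliferative zone at P2, genes of late chondrocyte differentiation were among those higher in the hypertrophic zone and some genes of the cell cycle among those lower. Col10a1, the type X collagen of hypertrophic cartilage, was 31446 ± 22108 CPM against 7.27 ± 8.43 CPM (SD, n = 4 each), a rise of 13.41 ± 2.69 on the log2 scale. Pth1r rose by 3.85 ± 0.60, Alpl by 6.89 ± 0.90, the immune checkpoint ligand Cd200 by 8.18 ± 1.72 and Frzb, a secreted Wnt binder, by 8.502 ± 1.53. Indian hedgehog (Ihh), the signal that prehypertrophic cells send to dividing ones, had a pooled ratio of 781 (267 to 3791) and bone sialoprotein (Ibsp) one of 589 (162 to 4874). Ratios were 4692 (841 to 185391) for the retinoic acid enzyme Aldh1a3, 1019 (182 to 40311) for the Wnt inhibitor Wif1 and 781 (139 to 30909) for the integrin Itga7. Cd200 and Wif1 are on the list of resting zone markers, yet were higher in hypertrophic sums. Ucma, also on that list, was lower. The sugar phosphate transporter Slc37a2 and the transcription factor Irx5, at 0 counts in proliferative sums, were at least 281-fold and 197-fold higher. The proliferation marker Mki67 had 0 counts in the hypertrophic sums and was at least 221-fold lower. Ucma, a secreted protein of early chondrocytes (-8.36 ± 1.13), the collagen-binding proteoglycans Prelp (-5.63 ± 0.76) and Fmod (-4.49 ± 0.71), chondromodulin, listed as Lect1 (-2.38 ± 0.58), and Lsp1 (-10.49 ± 1.69) fell as well. Tgfbi, a matrix protein induced by TGF-beta, had a pooled ratio of 0.0022 (4.53e-04 to 0.00643).

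**Figure D2:**
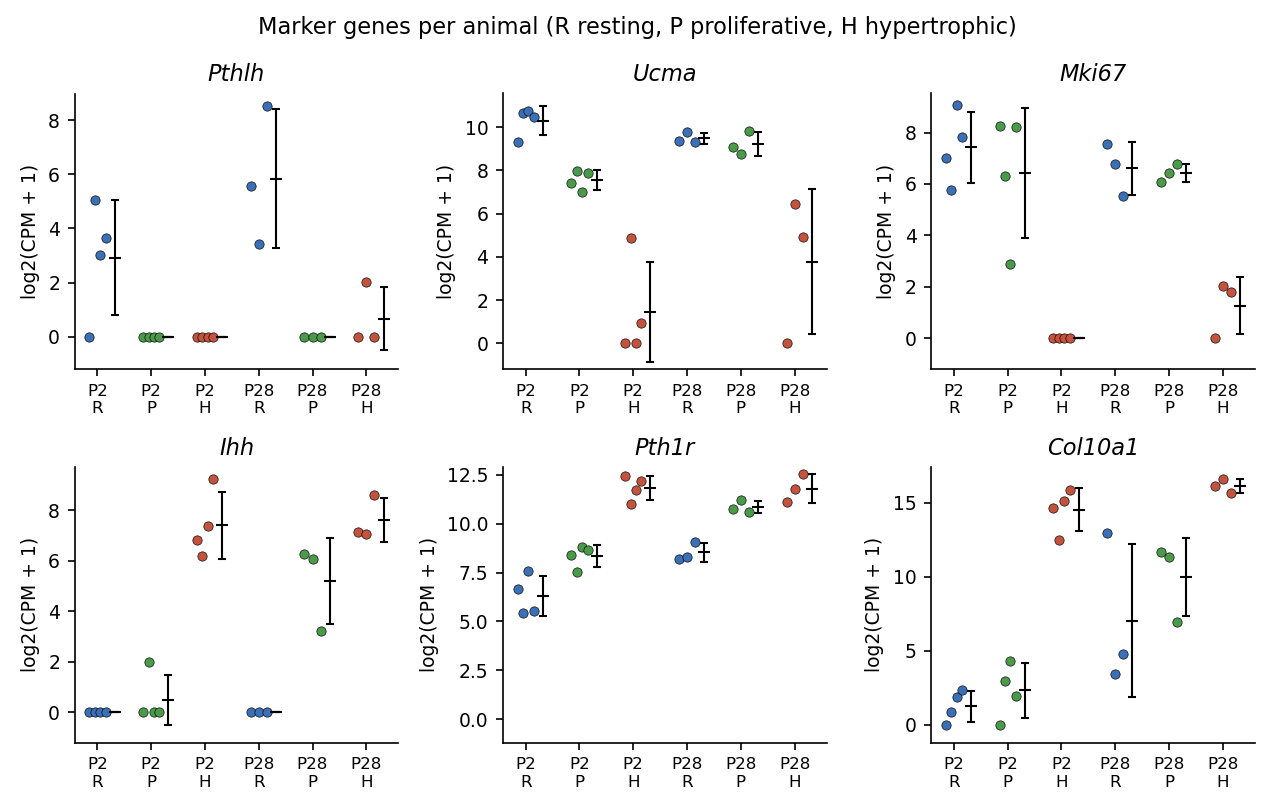
Levels of 6 marker genes on a log2(CPM + 1) axis, 1 point per animal sum, with the mean and SD of each age and zone (4 animals at P2 and 3 at P28). Ihh, Pth1r and Col10a1 lie highest in hypertrophic sums, Mki67 lowest there, and Col10a1 reached 7845 TMM-normalised CPM in the resting sum of P28 animal A.

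Altogether 161 of 6958 genes passed, 79 higher and 82 lower in hypertrophic, and the named ones had adjusted p of 1.69e-17 to 0.0464 (edgeR quasi-likelihood test, Benjamini-Hochberg, 3 animals with both zones). Col2a1, the main collagen of cartilage, was at 0.38 ± 0.36 (adjusted p = 0.733 in edgeR, Benjamini-Hochberg). The count fell to 75 without P2 animal A, 32 without P2 animal D, 28 without P2 animal G and 106 without P28 animal B, and was 309 without P28 animal D. DESeq2 gave 131 higher and 238 lower. Of the 39 named genes, 11 passed in every fit with 1 animal left out: Aldh1a3, Mki67, Lsp1, Ucma, Prelp, Fmod, Alpl, Pth1r, Frzb, Tgfbi and H19.

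Prehypertrophic and hypertrophic markers rose as a list, 8 of 18 members over all genes, with Runx3 as the 1 that fell, and the counts adjusted over the list alone were also 8 and 1 (camera, Benjamini-Hochberg adjusted p = 7.88e-09; adjusted p = 0.113 with an estimated correlation). Cell cycle genes fell, 7 of 31 over all genes and 15 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 5.12e-09; adjusted p = 0.176 with an estimated correlation). Among them Cenpf, a kinetochore protein, was at least 48.5-fold lower, and Top2a, the topoisomerase of dividing cells, had a pooled ratio of 0.003 (7.59e-05 to 0.0168). Hypertrophic sums held fewer detected genes than proliferative ones, 4401 against 6296 in P2 animal A, 8047 against 11212 in D and 8967 against 9622 in G. Counts outside Rn45s, Lars2 and Glra2 made up 15% against 36.5%, 51.7% against 83.4% and 58.2% against 77.6% in the same order. In the hedgehog pathway Ihh rose while its response genes Gli1 and Hhip, at 0 hypertrophic counts, were at least 63.1-fold and 33.7-fold lower. That is 1 higher and 2 lower of 14 over all genes and 1 and 4 adjusted over the list alone; the list as a whole did not pass (camera, Benjamini-Hochberg adjusted p = 0.268). Imprinted and juvenile growth genes fell, 5 of 17 over all genes and 6 adjusted over the list alone, with 1 higher in both counts (camera, Benjamini-Hochberg adjusted p = 0.007; adjusted p = 0.272 with an estimated correlation). H19 was at -3.79 ± 0.57, Meg3 at -2.68 ± 0.67 and Igf2, insulin-like growth factor 2, at -1.92 ± 0.55, while the cell cycle inhibitor Cdkn1c rose by 2.68 ± 0.67. Markers of other cells moved here too: the osteoblast and osteocyte genes Phex (7.29 ± 1.48) and Cgref1 (4.34 ± 1.18) and the haemoglobin chain listed as Beta-s (4.47 ± 1.29) were higher in hypertrophic sums. Other members past the threshold were Bmp2 (6.60 ± 1.95), Tgfb3 (5.85 ± 1.71), the protease inhibitor Timp3 (2.95 ± 0.82), the protease Adamts1 (5.15 ± 1.505) and, lower, the protease Mmp2 (-4.19 ± 1.12).

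Set directly against the hypertrophic zone at P2, the resting zone was higher in Ucma, by 10.81 ± 1.18, and in Igf2, by 1.94 ± 0.55, and Mki67 was at least 251-fold higher against 0 hypertrophic counts. Pth1r (-6.16 ± 0.67) and Col10a1 (-14.29 ± 2.72) were lower, and Ihh, at 0 resting counts, was at least 1618-fold lower. Col2a1, at -0.42 ± 0.35, and Nt5e, the ectonucleotidase CD73, at -0.05 ± 1.26, did not pass. The test called 262 of 6958 genes, 145 higher and 117 lower in resting, with adjusted p of 8.65e-17 to 0.0289 for the called genes named here (edgeR quasi-likelihood test, Benjamini-Hochberg, 3 animals with both zones). All 9 called members of the 18 prehypertrophic and hypertrophic markers were lower in resting, 11 adjusted over the list alone, and 8 of 31 cell cycle genes were higher, 16 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.49e-16 and 5.12e-09; adjusted p = 0.113 and 0.176 with an estimated correlation). Of the imprinted and juvenile growth genes 7 of 17 were higher, 8 higher and 1 lower adjusted over the list alone, and of the GH and IGF pathway 5 of 16, 7 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 7.39e-05 and 0.0192; adjusted p = 0.17 and 0.176 with an estimated correlation). Perichondrium and fibroblast markers leaned higher, with 2 higher and 1 lower of 7 and 5 and 1 adjusted over the list alone. Osteoblast and osteocyte markers and cholesterol synthesis genes leaned lower, with 3 and 0 past it and 3 and 0 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0383, 0.0264 and 1.14e-04; adjusted p = 0.45, 0.251 and 0.377 with an estimated correlation). The count was 163 without P2 animal A, 60 without P2 animal D, 54 without P2 animal G and 430 without P28 animal D.

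Signals from the resting zone hold back the maturation of chondrocytes further down the column. At P28, 4 resting zone markers rose in it, and members of the prehypertrophic list made up 6 of the genes that fell. Pthlh (GRCm38, chromosome 6, 147252101 to 147264183, minus strand), the PTHrP gene that keeps chondrocytes from maturing, had 109 counts in resting and 0 in proliferative sums, at least 99.6-fold higher. P28 animal D gave 98 of the counts, A 9 and B 2. Wif1 had a pooled ratio of 83.1 (27.6 to 411) and the matrix protein gene Efemp1 203 (35.3 to 8119). At P2 Wif1 was higher in hypertrophic than in proliferative sums. Apolipoprotein E (Apoe), 540.3 ± 90.5 against 16.7 ± 7.47 CPM (SD, n = 3 each), rose by 5.33 ± 1.28, the scavenger receptor Scara3 by 8.28 ± 1.76, the carboxypeptidase Cpm by 4.65 ± 1.17 and Meg3 by 5.04 ± 0.72. Lower in resting were Panx3 (-5.28 ± 0.91), Pth1r (-2.37 ± 0.57), the transcription factor Mef2c (-3.99 ± 0.85), the link protein Hapln1 (3839 ± 1791 against 14598 ± 2201 CPM), Col11a1 (-1.70 ± 0.42), the sphingomyelinase Smpd3 (-3.81 ± 0.74) and the imprinted zinc finger gene Plagl1 (-2.89 ± 0.60). The sphingomyelin synthase Sgms2 had a pooled ratio of 0.00116 (2.95e-05 to 0.00649), Cgref1 0.00908 (2.29e-04 to 0.051) and Sqle, squalene epoxidase of cholesterol synthesis, 0.0377 (0.00772 to 0.112). Ihh, the lactate carrier Slc16a3, the hypoxia-induced Ndufa4l2 and Samd4 had 0 resting counts and were at least 11.9-fold, 29.1-fold, 19.6-fold and 25.4-fold lower. For Samd4, 189 of the proliferative counts came from P28 animal D and 10 each from A and B.

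The threshold was passed by 39 of 6958 genes, 10 higher and 29 lower in resting, with adjusted p of 3.68e-12 to 0.0453 for the named ones (edgeR quasi-likelihood test, Benjamini-Hochberg, 3 animals with both zones). The median log2 change of all genes was -0.81, and RLE scaling moved it by 0.55 and gave 12 higher and 6 lower. Resting sums were shallower than proliferative ones, with 108601 against 339329 counts in P28 animal A, 135624 against 688270 in B and 260199 against 915624 in D. They held fewer detected genes, 6261 against 10324, 6844 against 11626 and 4209 against 7164 in the same order. After thinning to one total, 16 genes were higher and 21 lower, and DESeq2 gave 52 and 76. Ucma, at 0.15 ± 0.70, Col2a1, at -1.11 ± 0.36, and Sfrp5, at 3.10 ± 1.66, did not pass. Neither did Col10a1, which passed without P28 animal A. As CPM over the library total, without TMM, the tested resting library of that animal held 14199 CPM of Col10a1 and 433 CPM of Ibsp. Those of P28 animals B and D held 14.7 and 26.9 CPM of Col10a1. The count was 2 without the animal block, 10 without P2 animal D, 17 without P28 animal A, 5 without P28 animal B, 18 without P28 animal D. It was 8 without the 1 proliferative library of P28 animal D that holds Xist and 0 Y-linked counts. Of the 23 named genes, 2, Meg3 and Sgms2, passed in every fit with 1 animal left out.

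The resting zone markers rose as a list, 4 of 17 members over all genes (Wif1, Efemp1, Pthlh and Apoe) and 6 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.09e-06; adjusted p = 0.113 with an estimated correlation). Prehypertrophic and hypertrophic markers fell, 6 of 18 over all genes, and 7 fell and 1 rose adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0488; adjusted p = 0.503 with an estimated correlation). Glycolysis and hypoxia genes leaned lower (camera, Benjamini-Hochberg adjusted p = 1.13e-04, against 0.185 with an estimated correlation). Over all genes 2 of 21 fell, Ldha (-3.30 ± 0.84) and Aldoa (-3.64 ± 0.96), and 10 adjusted over the list alone. Chondrocyte matrix, cholesterol synthesis and amino acid response genes leaned lower, with 2, 1 and 0 members past the threshold over all genes and 10, 3 and 3 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00214, 0.00666 and 0.00104; adjusted p = 0.511, 0.505 and 0.13 with an estimated correlation). With no minimum on library counts the chondrocyte matrix list leaned the other way and did not pass (camera, Benjamini-Hochberg adjusted p = 0.921). The osteoblast and osteocyte markers fell, Cgref1 and Smpd3 among 5 tested, 3 adjusted over the list alone, and GH and IGF pathway genes leaned higher with 0 past the threshold and 1 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0106 and 0.00796; adjusted p = 0.217 and 0.176 with an estimated correlation).

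Between the hypertrophic and the proliferative zone at P28, the hypertrophic markers Alpl, Ibsp and Slc37a2 were higher, as at P2. Ibsp was 4261 ± 944 against 18.2 ± 14.3 CPM (SD, n = 3 each), a rise of 8.77 ± 1.32. Alpl rose by 2.94 ± 0.76, Timp3 by 4.12 ± 0.86, Phex, an endopeptidase on the list of osteoblast and osteocyte markers, by 5.97 ± 1.51, Frzb by 4.57 ± 1.19 and the chemokine receptor Cxcr7 by 7.23 ± 1.76. Slc37a2 and Vopp1, with 0 proliferative counts, were at least 89.1-fold and 17-fold higher. Irx5 and the lipase Lipg had pooled ratios of 254 (69.7 to 2113) and 160.1 (43.6 to 1334). Prelp (-4.36 ± 0.68), Ucma (-4.35 ± 0.84), Fmod (-2.77 ± 0.62), the proteoglycan Epyc (-3.57 ± 0.89), Scrg1 (-3.47 ± 0.83), H19 (-2.79 ± 0.56) and the glycolytic enzyme Tpi1 (-3.88 ± 0.90) were lower. Mki67 had a pooled ratio of 0.0268 (0.00322 to 0.0986). Tgfbi, with 0 hypertrophic counts, was at least 85.7-fold lower. So were Id2, an inhibitor of differentiation (22-fold), Slc16a3 (37.6-fold), Pkdcc (39.1-fold), Polr2d (58.9-fold), Mb21d2 (56-fold) and Fuca2 (11.9-fold). P28 animal D gave 348 of the proliferative counts of Polr2d, against 23 and 4 from B and A, and 338 of those of Mb21d2, against 8 and 10. Col10a1, at 72988 ± 23347 against 2007 ± 1661 CPM and 6.57 ± 2.07 on the log2 scale, did not pass at P28 (adjusted p = 0.272 in edgeR, Benjamini-Hochberg), nor did Ihh (2.15 ± 1.24) or Pth1r (0.88 ± 0.55). Col10a1 passed in 6 of 26 other fits, among them DESeq2, the test that is not robust, and the fit without P28 animal A.

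The count past the threshold was 78 of 6958 genes, 38 higher and 40 lower in hypertrophic, with adjusted p of 1.98e-07 to 0.0427 for the named ones (edgeR quasi-likelihood test, Benjamini-Hochberg, 3 animals with both zones). It was 10 without the animal block, 45 without P2 animal D, 18 without P28 animal A, 18 without P28 animal B and 41 without P28 animal D. By DESeq2, 71 were higher and 144 lower. Hypertrophic sums held fewer detected genes than proliferative ones here too, 5096 against 10324 in P28 animal A, 7916 against 11626 in B and 6424 against 7164 in D. Of the 25 named genes, 2, Tgfbi and Prelp, passed in every fit with 1 animal left out. Prehypertrophic and hypertrophic markers leaned higher (camera, Benjamini-Hochberg adjusted p = 2.37e-04, against 0.222 with an estimated correlation). Over all genes 3 of 18 members rose, and adjusted over the list alone 5 rose and 1 fell. Cell cycle and chondrocyte matrix genes leaned lower (camera, Benjamini-Hochberg adjusted p = 9.67e-06 and 0.0351, against 0.13 and 0.669 with an estimated correlation). Over all genes 1 of 31 and 3 of 23 members fell, and 4 and 9 adjusted over the list alone. Glycolysis and hypoxia, amino acid response and ribosomal protein genes leaned lower and immediate early and stress genes higher, with 1, 0, 0 and 0 members past the threshold over all genes, and adjusted over the list alone 2, 0, 0 and 2 in those directions, with 1 glycolysis gene higher (camera, Benjamini-Hochberg adjusted p = 0.0192, 0.0259, 0.0247 and 0.0141; adjusted p = 0.377, 0.292, 0.669 and 0.272 with an estimated correlation).

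Between the resting and the hypertrophic zone at P28, Ucma was higher in resting by 4.50 ± 0.83, Mki67 had a pooled ratio of 45.9 (12.2 to 386) and Igf2 of 33.6 (5.52 to 1378), while Pth1r was lower, at -3.25 ± 0.59, and Ihh, with 0 resting counts, was at least 56.7-fold lower. Of the Igf2 counts in resting, 23 came from P28 animal B, 2 from A and 1 from D, and Igf2 did not pass without P28 animal B. Col10a1, at -8.14 ± 2.49 (adjusted p = 0.201, edgeR with Benjamini-Hochberg), did not pass here but in 6 of 26 other fits, and Col2a1, at -0.44 ± 0.36, did not pass. The edgeR quasi-likelihood test called 123 of 6958 genes (Benjamini-Hochberg, 3 animals with both zones), 38 higher and 85 lower in resting, against 54 higher and 47 lower with RLE scaling, which moved the median of all genes by 0.44. DESeq2 gave 203 higher and 141 lower. Of the 18 prehypertrophic and hypertrophic markers 7 fell, and adjusted over the list alone 11 fell and 1 rose. Of the 17 resting zone markers 2 rose, Ucma and Apoe, and adjusted over the list alone 6 rose and 1 fell (camera, Benjamini-Hochberg adjusted p = 1.29e-07 and 2.05e-04; adjusted p = 0.13 and 0.14 with an estimated correlation). Cell cycle genes and the GH and IGF pathway leaned higher in resting, with 1 of 31 and 3 of 16 members higher, and adjusted over the list alone 7 higher, and 6 higher and 2 lower (camera, Benjamini-Hochberg adjusted p = 1.29e-07 and 0.0141; adjusted p = 0.113 and 0.176 with an estimated correlation). Osteoblast and osteocyte, cholesterol synthesis and immediate early genes leaned lower, with 2, 2 and 1 members lower and 4, 4 and 1 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00214, 8.85e-04 and 0.0457; adjusted p = 0.172, 0.433 and 0.45 with an estimated correlation). The count was 47 without the animal block, 73 without P2 animal D, 62 without P28 animal A, 28 without P28 animal B and 53 without P28 animal D.

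The zone effects at the 2 ages came from different animals but from 1 fit, which shares the dispersion of each gene. Calls at the ages are thus not independent, and the numbers for independent lists and the Fisher p-values serve as description only. The ages shared more called genes than independent lists would. Hypertrophic against proliferative had 28 genes higher at both ages against 0.431 for independent lists, among them Aldh1a3, Alpl, Frzb, Ibsp, Irx5, Phex, Slc37a2 and Timp3, and also Rn45s, Lars2 and the nuclear RNAs Malat1 and Neat1. It had 15 lower against 0.471, among them Fmod, H19, Lsp1, Mki67, Prelp, Scrg1, Tgfbi and Ucma, with 0 in opposite directions (Fisher's exact test, p = 6.90e-49 and 9.77e-20, across genes, which are not independent replicates). Resting against proliferative shared Meg3 as the 1 gene higher at both ages, against 0.0101, and 4 lower, Alpl, Panx3, Ppa1 and Pth1r, against 0.0458 (Fisher's exact test across genes, p = 0.01 and 7.87e-08). Resting against hypertrophic shared 19 higher and 44 lower, with 1 in opposite directions.

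**Figure D3:**
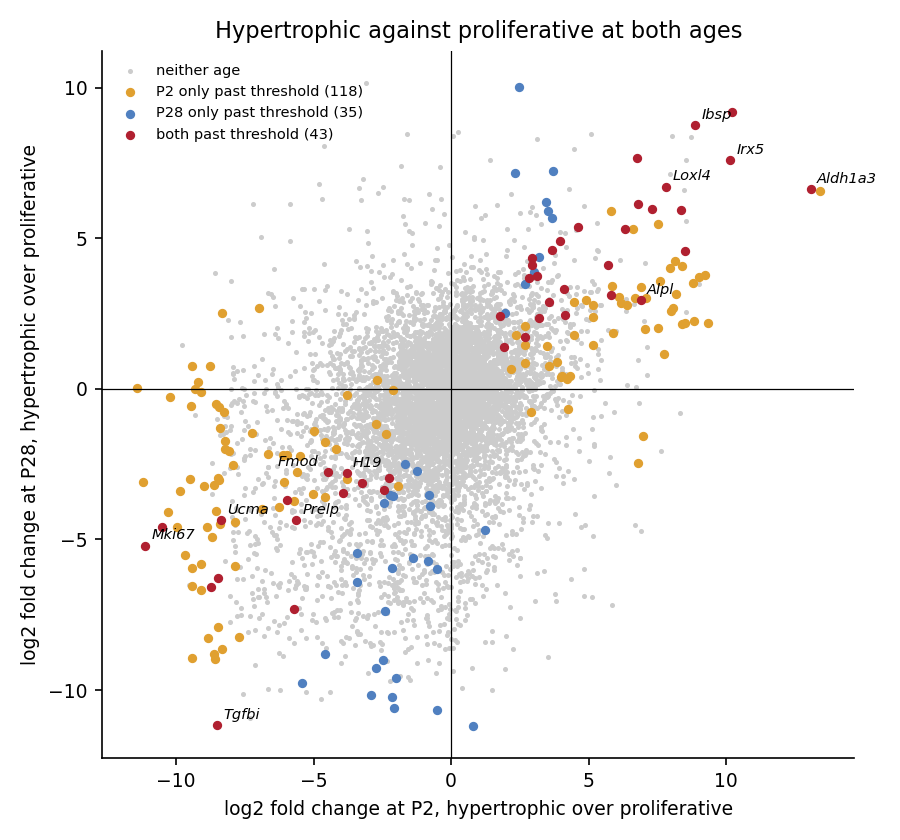
Fitted log2 fold change of hypertrophic over proliferative for each tested gene, P2 on the x axis and P28 on the y axis; colours mark genes past the threshold at P2, at P28 or at both ages. Genes past it at both ages lie in the upper right and lower left, 28 and 15 of them; fitted values of genes with few counts depend on the prior count.

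Growth of the skeleton slows between P2 and P28. Over these ages 4 imprinted growth genes fell in the resting zone, while of the secreted Wnt binders Wif1 rose and Sfrp1 fell. Igf2 (GRCm38, chromosome 7, 142650766 to 142666816, minus strand) was 42 ± 60.8 CPM at P28 (n = 3) against 5114 ± 3171 CPM at P2 (n = 4) and fell, at -6.69 ± 1.14 on the log2 scale. Dlk1, an imprinted inhibitor of differentiation, and the secreted Wnt binder Sfrp1 had 0 counts at P28 and were at least 223-fold and 47-fold lower, as were the lamin B receptor Lbr (20.2-fold) and Samd4 (25.7-fold). The imprinted Mest had a pooled ratio of 0.00323 (3.91e-04 to 0.0117). Epyc fell, at -3.93 ± 1.001. Hhip, a hedgehog-binding protein (8.93 ± 1.52), Apoe (5.98 ± 0.95), Wif1 (7.60 ± 1.48), the protease Htra1 (7.22 ± 1.29), insulin-like growth factor 1 (Igf1, 7.60 ± 1.75), Lsp1 (7.71 ± 1.54), the TGF-beta co-receptor Tgfbr3 (5.22 ± 1.28) and Vit, a matrix gene on the articular cartilage list (6.38 ± 1.44), rose. The transglutaminase F13a1 and the transporter Slc6a12 had 0 counts at P2 and were at least 1594-fold and 185-fold higher. For F13a1, 307 of the counts came from P28 animal D, 13 from A and 8 from B.

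In the resting zone 29 of 3327 genes passed, 19 higher and 10 lower at P28, against 46 higher and 59 lower in DESeq2, with adjusted p of 1.30e-05 to 0.05 for the named ones (edgeR quasi-likelihood test with the deposit set as a term, Benjamini-Hochberg). Pthlh (3.17 ± 1.39), Ucma (-0.63 ± 0.71), Sfrp5 (-0.28 ± 1.201), Pth1r (2.31 ± 0.86) and Mki67 (-0.37 ± 1.13) did not pass. Among the 19 is Glra2, a glycine receptor subunit, at 7.27 ± 0.94; its share of counts fell with depth over the 7 P2 animals (Spearman rho -0.857, exact p = 0.0238), and whether its rise belongs to the zone is left open. The count was 68 without P2 animal A, 14 without P2 animal D, 19 without P2 animal F and 13 without P2 animal G, and 0 within set A alone. Of the 17 named genes 5 passed in every fit with 1 animal left out: Hhip, Dlk1, Mest, Igf2 and Apoe.

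Imprinted and juvenile growth genes fell in the resting zone, 4 of 14 over all genes (Plagl1, Dlk1, Mest and Igf2) and 7 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 5.12e-09; adjusted p = 0.214 with an estimated correlation). The resting zone markers leaned higher, with 2 of 10 past the threshold, Wif1 and Apoe, and 3 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.24e-04; adjusted p = 0.256 with an estimated correlation). Chondrocyte matrix, hypertrophic marker and ribosomal protein genes leaned higher and glycolysis and hypoxia genes lower, with 1 gene, Epyc, past the threshold, and it fell (camera, Benjamini-Hochberg adjusted p = 0.0141, 0.0141, 0.0141 and 0.0244; adjusted p = 0.485, 0.292, 0.675 and 0.529 with an estimated correlation). Adjusted over the list alone, 2 matrix members rose and 2 fell, 2 hypertrophic markers rose, and of the glycolysis genes 1 rose and 3 fell.

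In the proliferative zone Igf2 fell with age, as in the resting zone. It was 7.51 ± 6.51 CPM at P28 (n = 3) and 3059 ± 1824 CPM at P2 (n = 4), at -8.98 ± 0.75 on the log2 scale. H19, the non-coding RNA next to it (-3.90 ± 0.50), Meg3 (-4.91 ± 0.89) and the zinc finger genes Zfp275 (-5.16 ± 1.40) and Zfp518a (-4.69 ± 1.26) fell. Dlk1, with 0 counts at P28, was at least 44.6-fold lower and the glypican Gpc3 had a pooled ratio of 0.00516 (1.30e-04 to 0.0289). Of the cartilage matrix, Col2a1 rose by 1.62 ± 0.26, Hapln1 by 1.83 ± 0.36 and Comp by 2.05 ± 0.43. Col12a1 rose by 3.35 ± 0.74. Of the prehypertrophic and hypertrophic markers Col10a1 rose by 7.37 ± 0.76, Alpl by 4.87 ± 1.17 and Pth1r by 2.27 ± 0.57. As CPM over library totals, without TMM, Col10a1 varied between P28 animals. It was at 513 to 6058 CPM in the tested libraries of A and B and 103 and 45.6 CPM in those of D. Tested P2 libraries held 0 to 24.4 CPM. Outside the tests, xylene libraries held 5.58, 4.05 and 51 CPM in P28 animal D and 2076 and 1516 CPM in P28 animal E. Smpd3, of the osteoblast and osteocyte list, rose by 3.11 ± 0.55, the BMP antagonist Chrdl1 by 6.60 ± 1.35 and the ion pump subunit Fxyd2 by 4.66 ± 1.01, and the sorting receptor Sort1 had a pooled ratio of 278 (76.2 to 2314).

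Here 32 of 4712 genes passed, 20 higher and 12 lower at P28, against 14 higher and 21 lower with RLE scaling, which moved the median of all genes by -0.13, and 19 and 24 in DESeq2. The named genes had adjusted p of 3.36e-29 to 0.0379 (edgeR quasi-likelihood test with the deposit set as a term, Benjamini-Hochberg). The count was 49 without P2 animal A, 16 without P2 animal D, 15 without P2 animal E, 15 without P2 animal G. It was 6 without P28 animal A, 12 without P28 animal B, 20 without P28 animal D and 14 without that animal's library that holds Xist. Of the 18 named genes 4 passed in every fit with 1 animal left out: Col10a1, Igf2, H19 and Smpd3. The imprinted and juvenile growth genes fell, 5 of 13 over all genes, and adjusted over the list alone 6 fell and 1 rose (camera, Benjamini-Hochberg adjusted p = 5.12e-09; adjusted p = 0.17 with an estimated correlation). Chondrocyte matrix genes leaned higher, with 6 of 23 past the threshold over all genes and 1, Matn1, lower, and adjusted over the list alone 12 rose and 1 fell. Of the hypertrophic markers 3 of 12 rose, 3 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00108 and 8.37e-04; adjusted p = 0.521 and 0.292 with an estimated correlation). Perichondrium and fibroblast markers leaned higher with 0 members past the threshold and 1 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0388; adjusted p = 0.496 with an estimated correlation).

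In the hypertrophic zone 2 of 1963 genes passed with age. Ibsp rose by 3.31 ± 0.76, from 459.8 ± 394 CPM at P2 (n = 4) to 4261 ± 944 CPM at P28 (n = 3), and Igf2 fell, with 1 count at P28 and a pooled ratio of 6.81e-04 (1.72e-05 to 0.0038) (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0495 and 4.90e-06). Ihh (-0.05 ± 0.91), Pth1r (-0.21 ± 0.70) and Col10a1 (1.33 ± 0.77) did not pass. The count was 1 without P2 animal D, P2 animal G, P28 animal A, P28 animal B or P28 animal D, and Igf2 passed in each of these fits. The chondrocyte matrix list leaned higher with 0 of 20 members past the threshold and 5 adjusted over the list alone. The imprinted genes and the GH and IGF pathway leaned lower, with Igf2 as their 1 member past it and 2 and 1 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 7.88e-06, 0.0059 and 0.0383; adjusted p = 0.505, 0.496 and 0.352 with an estimated correlation).

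**Figure D4:**
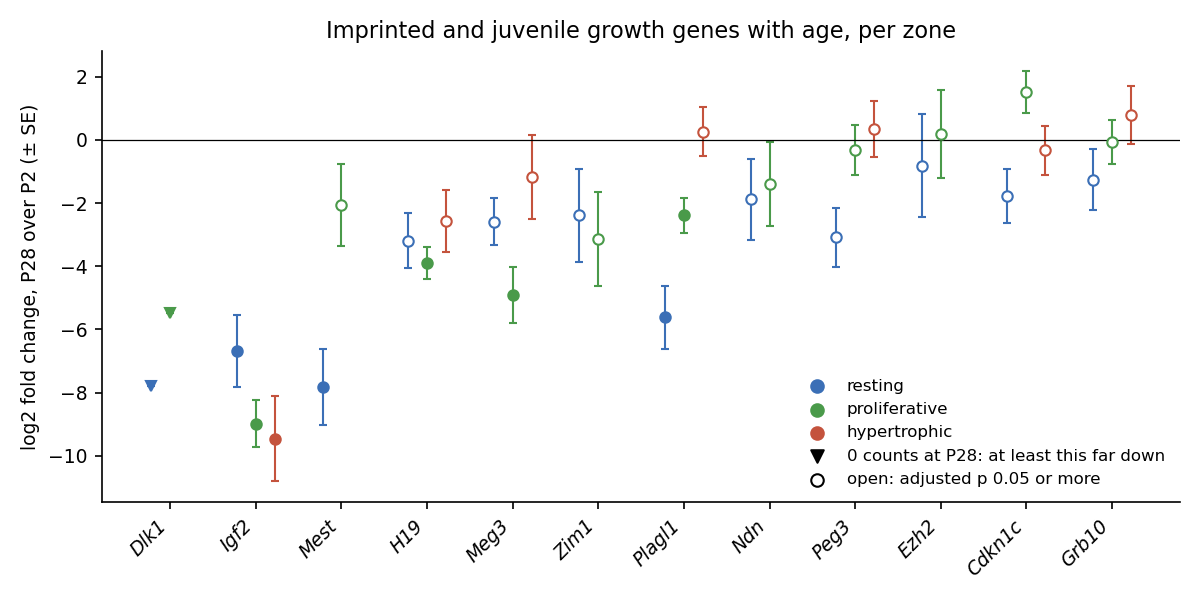
Log2 fold change of P28 over P2 for tested imprinted and juvenile growth genes in each zone, with SE bars; filled points passed the threshold and triangles give the bound for genes with 0 counts at P28. Igf2 passed in all 3 zones, at -6.69 in resting and -8.98 in proliferative sums, while its hypertrophic point rests on 1 count at P28.

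The difference between ages in the zone effect itself was tested last. For resting against proliferative, 10 of 6958 genes had a zone effect that changed with age (edgeR quasi-likelihood interaction test, Benjamini-Hochberg adjusted p = 1.48e-04 to 0.0436), 3 towards resting at P28 and 7 away from it, against 1 and 1 with RLE scaling, which moved the median of all genes by 0.57. The 3 were Gdf10, Pcsk6 (6.75 ± 1.69) and Lsp1 (6.61 ± 1.61). The 7 were Dcn (-5.01 ± 1.25), the calpain Capn6 (-5.07 ± 1.25), Epyc (-5.70 ± 1.23), Mest, Sgms2, Fat3 and Samd4. Fitted values of Gdf10, Mest, Sgms2, Fat3 and Samd4 rest on a group with 0 to 3 counts. Pthlh cannot be compared this way, with 0 proliferative counts at both ages, and Pth1r, at -0.06 ± 0.81, did not pass. The count was 5 without P2 animal A, 6 without P2 animal C, 3 without P2 animal D, and 1 without P2 animal G. Other fits gave 5 without P28 animal A, 6 without P28 animal B, 3 without the Xist-holding library of P28 animal D and 2 without the animal block. None, 0 of the 10, passed in every fit with 1 animal left out. Perichondrium and fibroblast markers leaned away from resting with age as a list, with 1 of 7, Dcn, past the threshold over all genes and 3 adjusted over the list alone; Dcn kept its call in 2 of 26 other fits. Glycolysis and hypoxia genes leaned the same way as a list, while the median of all genes was at -0.98, with 0 of 21 past the threshold and 2 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00387 and 0.0192; adjusted p = 0.292 and 0.415 with an estimated correlation).

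For hypertrophic against proliferative, edgeR called 0 of 6958 genes with an age difference. By edgeR 413 had an unadjusted p under 0.05, DESeq2 called 74 and limma voom 0, and edgeR called 1 without P28 animal A and 10 without P28 animal D. Pth1r, at -2.96 ± 0.78, and Ucma, at 4.01 ± 1.33, were not past the threshold. The prehypertrophic and hypertrophic markers as a list leaned towards a smaller difference at P28, with 0 of 18 members past the threshold and 4 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0077; adjusted p = 0.352 with an estimated correlation).

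For reference, the positions of further genes named above in GRCm38 are Ihh at chromosome 1, 74945315 to 74951672, Pth1r at chromosome 9, 110722085 to 110747145, Col10a1 at chromosome 10, 34389981 to 34397085, Ibsp at chromosome 5, 104299171 to 104311469, and Ucma at chromosome 2, 4976122 to 4985748. Others are Mki67 at chromosome 7, 135689784 to 135716361, Panx3 at chromosome 9, 37659902 to 37669235, and Dcn at chromosome 10, 97479609 to 97518143. Gdf10 is at chromosome 14, 33923587 to 33937983, Apoe at chromosome 7, 19696109 to 19699188, Hhip at chromosome 8, 79965851 to 80058006, Dlk1 at chromosome 12, 109452823 to 109463336, Meg3 at chromosome 12, 109541001 to 109571726 and H19 at chromosome 7, 142575529 to 142578143. All are protein-coding apart from Meg3 and H19, which are long non-coding RNAs.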

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

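All tests of explanations in this part were chosen after the results were seen. A value far from the rest of its group was found in 7 of 59 groups, where about 1 in 20 groups, 2.95 here, would show one by chance. These are Sfrp5 at 10.2 CPM in the hypertrophic sum of P2 animal G, Ihh at 2.97 CPM in the proliferative sum of P2 animal D, Mmp13 at 14.2 CPM in the hypertrophic sum of P2 animal C and Ptch1 at 37.4 CPM in the hypertrophic sum of P2 animal A. For Sfrp5, Ihh and Mmp13 all other sums of the group held 0, where any value above 0 is flagged. Among libraries they are Col2a1 at 70.3 CPM in P28 hypertrophic xylene replicate 3, Col2a1 at 4924 CPM in P28 resting xylene replicate 2, and a total of 872 counts in P28 proliferative replicate 7.

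A difference between the ages in the resting against proliferative effect marked 10 genes: Sgms2 (-8.38), Samd4 (-14.05), Epyc (-5.70), Gdf10 (10.05), Mest (-6.70), Fat3 (-13.76), Lsp1 (6.61), Capn6 (-5.07), Dcn (-5.01) and Pcsk6 (6.75), as fitted log2 differences, several of which rest on groups with 0 to 3 counts. The same kind of difference marked the lists glycolysis and hypoxia (camera, Benjamini-Hochberg adjusted p = 0.0192; adjusted p = 0.415 with an estimated correlation) and perichondrium and fibroblast (camera, adjusted p = 0.00387; adjusted p = 0.292 with an estimated correlation), and for hypertrophic against proliferative the prehypertrophic and hypertrophic markers (camera, adjusted p = 0.0077; adjusted p = 0.352 with an estimated correlation). Signals in libraries outside the tests were Col10a1 at 32069 CPM and Igf2 at 2774 CPM in the P3 hypertrophic library, Col1a1 at 62781 CPM in P28 hypertrophic xylene replicate 3 and Col10a1 at 72298 CPM in P28 hypertrophic xylene replicate 5.

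Glra2 rose with age in the resting zone by 7.27 ± 0.94. Its share of the counts fell as the other counts rose over the 7 P2 animals, 5 of set A and 2 of set B (Spearman rho -0.857, exact p = 0.0238; Pearson r -0.837, exact p = 0.0409; 5 relations were computed). Without the 2 farthest animals r was -0.828 and rho -0.6. A background that takes a larger share in captures with few other counts may explain part of it. Libraries under the count minimum had high shares in other zones and at both ages, 39% in P2 proliferative replicate 3 and 85.8% in P28 hypertrophic replicate 7. Also under it, P2 animal E resting (57987 other counts) had 6.79%, above 3.28% in P28 resting replicate 2 (63512). The 1 pair of tested sums with other counts within 25% of each other was P2 animal A (148004) and P28 animal D (142839). There the shares were 0.0325% and 3.58%, 110.1 times apart. The pairs go both ways, and 1 animal per age leaves this open. A rise with age was compared in libraries of at least 500000 counts, where the lowest of 2 P28 shares was 1.53 times the highest of 3 P2 shares; the 2 are xylene and the 3 ethanol libraries, so age and fixation cannot be told apart, and the ethanol P28 sums in which the rise was called are not among them.

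Rn45s and Lars2 rose together in the hypertrophic zone. If Lars2 counts were ribosomal RNA reads, the shares should follow each other in each zone; Spearman's rho over 7 animals was 0.536 in resting (exact p = 0.236), 0.893 in proliferative (exact p = 0.0123) and 0.357 in hypertrophic sums (exact p = 0.444), which cannot tell. A property of the zone present in every animal was tested by the Rn45s share. It was higher in hypertrophic than in proliferative in 6 of 8 animals, so the measured shares go against a rise in every animal. Whether the zones differ in most animals the sign test cannot tell (exact sign test p = 0.289). The share was not higher in P3 animal A (26.5% against 37.4%) and P28 animal E (12.6% against 25.4%). In animal E 1 proliferative library held 78.7% and another 12.9%. Nor was it higher in the xylene libraries of P28 animal D (27% against 27.5%), which is counted as higher by its ethanol libraries (81% against 53.5%).

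A proliferative library of P28 animal D holds 267 Xist counts, 1021 CPM of the counts outside Rn45s, Lars2 and Glra2, against 513 to 3924 in 13 libraries of P28 animals A, B and E. Of the 14 other libraries of animal D, 11 had at most 14.7; the other 3, with 1995 to 13080 such counts, reached 152.9, from 2 Xist counts in a library with 0 Y-linked counts. At the lowest Y-linked rate of the 11, from 4 counts in an ethanol library of the same zone, 9.13 would be expected here (2.49 at the low end of its 95% interval), at the rates of the other 10 59.8 to 153, and 0 were seen (exact conditional probability of 0 against the lowest = 0.00861; counting error only). A library of another animal could explain this. The criterion was at least 3 expected Y-linked counts with 0 seen, and more Xist than in the 11. The criterion as written named the lowest rate itself, where it was met (9.13). The value tested was the stricter low end of that rate's interval (2.49), where it was not met, so this is left open. A mixture made mostly of RNA from animal D is open only at that rate, where 0 Y-linked counts allow up to 66.4% of it, against up to 6.22% at the next lowest. The library gave 613885 of the 915624 counts of the tested proliferative sum of animal D. If the library is of another animal, P28 zone comparisons that use this sum pair zones of different animals.

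Regrouping the sums gave the following. For P28 against P2, 1 of 34 splits in resting, the real one, had as many called genes as the real 29 (highest other 24). In proliferative 1 of 35, again the real one, had as many as the real 32 (highest other 23). Both shares are under 0.05, but they are the lowest that so few splits can give. They were not adjusted over the comparisons regrouped, so chance is made less likely and not excluded. In hypertrophic 3 of 35 splits reached the real 2 (highest other 2), so chance cannot be excluded. Each zone comparison had 4 splits, too few for a share under 0.05, and in each 1 split, the real one, had as many: 18, 161 and 262 at P2 for resting against proliferative, hypertrophic against proliferative and resting against hypertrophic (highest other 0, 1 and 0), and 39, 78 and 123 at P28 (highest other 1, 0 and 0). The age differences had 10 splits each, too few as well, with 1 as high as the real 10 (highest other 1) and 10 as high as the real 0 (highest other 0).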

How the results depend on the processing

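Of the alternatives below, 4 were chosen after the data were seen: without Rn45s, Lars2 and Glra2, without each of a pair of doubted libraries, and thinned sums; the others were fixed in advance. A minimum of 1000000 counts and set B alone were not run in any of the 11 comparisons. Genes called were 18 for resting against proliferative at P2, 161 for hypertrophic against proliferative at P2, 262 for resting against hypertrophic at P2, 39 for resting against proliferative at P28, 78 for hypertrophic against proliferative at P28, 123 for resting against hypertrophic at P28, 29 for P28 against P2 in resting, 32 for P28 against P2 in proliferative, 2 for P28 against P2 in hypertrophic, 10 for age difference of resting against proliferative and 0 for age difference of hypertrophic against proliferative. Named genes past the threshold turned direction in 1 gene and setting, Pcsk6 without the animal block, and list tests past it in 1. With RLE 121 of 161 named calls stayed past the threshold, with DESeq2 139 of 161, with set A alone 78 of 158, without P2 animal D 79 of 158, without the animal block 58 of 124, with no count minimum 75 of 143, and without P28 animal B 88 of 161. Thinning all sums to the lowest total kept the zone counts within 1.5 times: 19 and 37 for resting against proliferative at P2 and P28, 121 and 69 for hypertrophic against proliferative, and 180 and 117 for resting against hypertrophic. After thinning, P28 against P2 had 26 calls in resting, 12 in proliferative and 4 in hypertrophic, and the age differences had 6 for resting against proliferative and 0 for hypertrophic against proliferative. The alternative with xylene libraries holds P28 hypertrophic xylene replicate 3, which has 70.3 CPM of Col2a1 and 418.3 CPM of Igf2, and the one with the P3 animal holds a library with both Xist and Y-linked counts. Below, R, P and H stand for the resting, proliferative and hypertrophic zones, R/P for one against the other, age R for P28 against P2 in resting, and change of R/P for the difference between the ages.

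The replicate block is the animal. With no replicate block, the counts were 13 for R/P at P2, 205 for H/P at P2, 309 for R/H at P2, 2 for R/P at P28, 10 for H/P at P28, 47 for R/H at P28, 2 for change of R/P and 0 for change of H/P. The cause was not tested.

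Counts that moved by over 1.5 times follow by setting. DESeq2 gave 33 for R/P at P2, 369 for H/P at P2, 472 for R/H at P2, 128 for R/P at P28, 215 for H/P at P28, 344 for R/H at P28, 105 for age R, 21 for age H, 44 for change of R/P and 74 for change of H/P. No count minimum gave 32 for R/P at P2, 436 for R/H at P2, 11 for R/P at P28, 22 for H/P at P28, 13 for age R, 1 for age P, 0 for age H and 3 for change of R/P. P3 counted with P2 gave 46 for R/P at P2, 331 for H/P at P2, 529 for R/H at P2, 56 for age R, 54 for age P, 11 for age H and 2 for change of H/P. Voom with quality weights, libraries not summed gave 64 for R/P at P2, 515 for R/H at P2, 286 for H/P at P28, 53 for age R, 64 for age P, 7 for age H and 2 for change of R/P. No filter on low counts gave 89 for H/P at P2, 165 for R/H at P2, 14 for R/P at P28, 48 for H/P at P28, 64 for R/H at P28, 62 for age R, 13 for age P, 1 for age H and 5 for change of R/P. Ethanol and xylene libraries gave 261 for H/P at P2, 415 for R/H at P2, 69 for age R, 7 for age H and 15 for change of H/P. Set A only gave 73 for H/P at P2, 129 for R/H at P2, 20 for R/P at P28, 72 for R/H at P28, 0 for age R, 6 for change of R/P and 4 for change of H/P. RLE normalization gave 18 for R/P at P28 and 2 for change of R/P. Not robust gave 23 for R/P at P28, 12 for age P, 1 for age H, 6 for change of R/P and 1 for change of H/P. Animal label as given gave 70 for R/P at P28, 141 for H/P at P28, 1 for age H and 5 for change of H/P. Minimum of 5000 genes gave 20 for R/P at P28, 81 for R/H at P28, 21 for age P and 6 for change of H/P. Without the P28 animal D proliferative library that holds Xist gave 8 for R/P at P28, 14 for age P and 3 for change of R/P. Strict filter on low counts gave 48 for age R, 11 for age H and 6 for change of R/P. No deposit set term gave 54 for age P and 1 for age H. Animal sums thinned to one total gave 12 for age P, 4 for age H and 6 for change of R/P. The cause was not tested.

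With 1 animal left out, called genes ranged as follows: R/P at P2 5 (without P2 animal D) to 39 (without P28 animal D), H/P at P2 28 (without P2 animal G) to 309 (without P28 animal D), R/H at P2 54 (without P2 animal G) to 430 (without P28 animal D), R/P at P28 5 (without P28 animal B) to 39 (without P2 animal E), H/P at P28 18 (without P28 animal A) to 80 (without P2 animal F), R/H at P28 28 (without P28 animal B) to 129 (without P2 animal E), age R 13 (without P2 animal G) to 68 (without P2 animal A), age P 6 (without P28 animal A) to 49 (without P2 animal A), age H 1 (without P2 animal D) to 2 (without P2 animal A), change of R/P 1 (without P2 animal G) to 12 (without P28 animal D), change of H/P 0 (without P2 animal A) to 10 (without P28 animal D). The cause was not tested.

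Values with the opposite direction, log2 changes for genes and for the chondrocyte matrix list the camera Benjamini-Hochberg adjusted p, none of them past the threshold, follow by setting. No count minimum: chondrocyte matrix in R/P at P28 0.921, Col2a1 in R/P at P2 1.14, Mki67 in R/P at P2 0.58, Col2a1 in R/H at P2 0.93, Col2a1 in R/P at P28 0.28, Mki67 in R/P at P28 -0.11, Ptch1 in R/P at P28 0.48, Gli1 in H/P at P28 0.0867, Igf2 in H/P at P28 0.12, Col2a1 in R/H at P28 0.76, Ihh in age H 0.00809, Mki67 in change of R/P -0.68, Igf2 in change of R/P -0.64, Ptch1 in change of H/P 0.44, Igf2 in change of H/P 1.65. No replicate block: Pcsk6 in R/P at P2 0.33, Col2a1 in R/P at P2 0.57, Mki67 in R/P at P2 0.16, Col2a1 in R/H at P2 0.43, Ptch1 in R/H at P2 0.0671, Nt5e in R/H at P2 0.0163, Col10a1 in R/P at P28 0.38, Ptch1 in R/P at P28 1.04, Col10a1 in change of R/P 1.41. Voom with quality weights, libraries not summed: Col2a1 in R/P at P2 0.61, Col2a1 in H/P at P2 -0.28, Col2a1 in R/H at P2 0.89, Ptch1 in R/H at P2 1.09, Nt5e in R/H at P2 0.28, Ptch1 in R/P at P28 0.044, Col2a1 in R/H at P28 0.21, Mki67 in age R 0.46, Pth1r in change of R/P 0.0478, Ptch1 in change of H/P 1.30, Igf2 in change of H/P 1.54. RLE normalization: Igf2 in R/P at P2 -0.069, Ptch1 in R/P at P28 0.20, Col2a1 in R/H at P28 0.00353, Pth1r in change of R/P 0.65. Strict filter on low counts: Igf2 in R/P at P2 -0.00424, Col2a1 in age R -0.0287, Ihh in age H 0.0698. DESeq2: Igf2 in R/P at P2 -0.0684, Ptch1 in R/P at P28 0.44, Col2a1 in R/H at P28 0.00346, Pth1r in change of R/P 0.67, Col10a1 in change of R/P 0.11. Ethanol and xylene libraries: Igf2 in R/P at P2 -0.0458, Ptch1 in R/P at P28 2.09, Igf2 in H/P at P28 2.86, Nt5e in R/H at P28 -0.0688, Igf2 in change of H/P 4.87. Minimum of 5000 genes: Igf2 in R/P at P2 -0.0216, Ptch1 in R/H at P2 3.67, Nt5e in R/H at P2 0.47, Ptch1 in R/P at P28 0.33, Gli1 in R/P at P28 -1.57, Col2a1 in R/H at P28 0.32, Mki67 in age R 0.62, Pth1r in age H 0.14, Col10a1 in change of R/P 0.80. P3 counted with P2: Igf2 in R/P at P2 -0.0761, Ptch1 in R/H at P2 1.17, Nt5e in R/H at P2 0.35, Ihh in age H 0.0279, Pth1r in age H 0.0317, Col10a1 in change of R/P 2.17. Set A only: Igf2 in R/P at P2 -0.0934, Col2a1 in H/P at P2 -0.10, Ptch1 in H/P at P2 1.27, Nt5e in R/H at P2 1.30, Ptch1 in R/P at P28 0.43, Gli1 in R/P at P28 -1.45, Col2a1 in R/H at P28 0.23, Mki67 in age R 0.71, Nt5e in age P -0.86, Col10a1 in change of R/P 2.10, Igf2 in change of H/P 0.99. Animal sums thinned to one total: Igf2 in R/P at P2 -0.0835, Pth1r in change of R/P 0.73, Nt5e in change of R/P -0.54, Igf2 in change of H/P 0.86, Nt5e in change of H/P -1.45. No filter on low counts: Nt5e in R/H at P2 0.0922, Col2a1 in age R -0.27. Animal label as given: Ptch1 in R/P at P28 0.000521, Nt5e in age P -0.19. Without the P28 animal D proliferative library that holds Xist: Nt5e in R/P at P28 0.64, Nt5e in age P -0.96, Pth1r in change of R/P 0.49. No deposit set term: Col2a1 in age R -0.16, Ihh in age H 0.0174. The cause was not tested.

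With 1 animal left out, the lowest and highest log2 values of genes whose direction turned, none past the threshold with all animals, were -0.35 to 0.41 for Col2a1 in R/P at P2, -2.59 to 0.45 for Col10a1 in R/P at P2, -0.10 to 0.0938 for Igf2 in R/P at P2, -0.11 to 0.65 for Col2a1 in H/P at P2, -0.74 to 3.58 for Ptch1 in R/H at P2, -0.84 to 1.11 for Nt5e in R/H at P2, -0.0525 to 0.54 for Ucma in R/P at P28, -5.39 to 0.52 for Col10a1 in R/P at P28, -0.48 to 0.97 for Mki67 in R/P at P28, -4.65 to 0.56 for Ptch1 in R/P at P28, -1.56 to 3.03 for Gli1 in R/P at P28, -0.14 to 3.74 for Igf2 in R/P at P28, -5.74 to 0.17 for Sfrp5 in H/P at P28, -0.93 to 0.36 for Col2a1 in R/H at P28, -0.79 to 2.14 for Sfrp5 in age R, -0.70 to 0.74 for Col2a1 in age R, -1.26 to 0.62 for Mki67 in age R, -0.96 to 1.53 for Nt5e in age P, -0.16 to 0.10 for Ihh in age H, -0.70 to 0.15 for Pth1r in age H, -0.36 to 0.25 for Pth1r in change of R/P, -4.52 to 1.39 for Col10a1 in change of R/P, -2.02 to 3.20 for Ptch1 in change of R/P, -0.0766 to 4.53 for Gli1 in change of R/P, -0.17 to 3.79 for Igf2 in change of R/P, -0.0064 to 1.64 for Nt5e in change of R/P, -1.86 to 5.47 for Sfrp5 in change of H/P, -4.23 to 0.68 for Igf2 in change of H/P, -1.203 to 1.40 for Nt5e in change of H/P. Of these, Col10a1 in R/P at P28 passed the threshold without P28 animal A, and Igf2 in R/P at P28 and in the change of R/P passed it without P28 animal D. The cause was not tested.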

Other observations

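No test in this part was chosen after the results were seen, since it gives values without tests. The P3 animal, counted in no comparison of the report, had Igf2 at 8595 CPM in resting, 7155 CPM in proliferative and 2774 CPM in hypertrophic captures, and Col10a1 at 191.6 CPM in proliferative and 32069 CPM in hypertrophic captures. In its resting library Col10a1 was 0.917 CPM, under the floor of 1.37 CPM set by 3 counts. Each value is the CPM of 1 library over its total. The proliferative library holds 355 Xist and 311 Y-linked counts, and the other 2 hold 0 Xist counts, so whether all 3 come from 1 animal is in doubt.

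Xylene-fixed libraries of P28 animal D had Col10a1 at 9601, 19860, 32.9 and 65447 CPM in replicates 1 to 4 labelled hypertrophic and Col1a1, a collagen of bone, at 28, 8.17, 62781 and 40.7 CPM in the same order. In replicate 3 Igf2 was 418.3, Col2a1 70.3, Acan 386, Postn 10143 and Ibsp 18425 CPM, where Col2a1 was at least 39390.3 CPM in the other xylene captures labelled hypertrophic, so its own markers go against its label. In resting replicates 1 to 3 of that animal Col10a1 was 926.8, 671.5 and 8.66 CPM, where the floor of 3 counts was 926.8, 111.9 and 2 CPM. In proliferative replicates 1 to 3 Col10a1 was 5.58, 4.05 and 51 CPM. P28 animal E had Col10a1 at 31.7 CPM in resting, 2076 and 1516 CPM in proliferative and 72298 CPM in hypertrophic xylene captures.

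Lists with 0 members past the threshold in any comparison were Wnt response (5 of 13 members tested), oxidative phosphorylation (30 of 32), osteoclast (2 of 12), macrophage and monocyte (1 of 14), endothelium (1 of 12), skeletal muscle (3 of 14), neutrophil and granule (0 of 13) and adipocyte (0 of 7).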
